A study of Homo sapiens with 6 samples.

How the data were processed

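Expression was measured on Affymetrix whole-transcript arrays in 6 samples of 2 lines, T24 and its pirarubicin-resistant derivative T24/THP, with 3 biological replicates each per the labels. Total RNA was amplified and turned into biotin-labelled cDNA with the Affymetrix WT PLUS kit, per the labels' protocols. The deposited values are log2 intensities, 1 per transcript cluster and array. Affymetrix Expression Console is named by the submitters' processing notes, and its version, algorithm and settings are not given in the sources used here. The values behave as normalized data, since the 6 arrays had medians of 3.71 to 3.79 and upper quartiles of 5.47 to 5.59 log2 units. Coordinates are those of the deposited annotated table, whose text names GRCh37.

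The annotated table holds 65854 transcript clusters, of which 26515 have exactly 1 gene symbol, 168 several and 39171 none. The deposited series table holds 70523 rows, of which 4669 are not in the annotated table. Only 1674 of those 4669 are transcript clusters. The values of shared transcript clusters differed by at most 0.00005 log2 units. Only transcript clusters with 1 symbol were tested. Symbols were updated through a RefSeq table of assembly GRCh38.p14 used for names only, by accession for 22674, as a current symbol for 1997 and through a unique synonym for 922, while 922 kept the name in the file. This changed 3656 symbols. Of 610 genes with several transcript clusters, the one with the highest mean over all arrays was used, which gave 24930 genes. No filter on low values was applied. Every column of per-sample values was matched to a label.

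The background range was read from 23 background control probe sets in the deposited series table. Its upper bound was the mean over a line's arrays of the brightest of them, 5.54 in T24 and 5.51 in T24/THP. This bound is strict, since the median of these probe sets was 2.65 to 2.86 over the arrays. T24 replicate 3 raised the T24 bound, with a brightest probe set at 6.38 against 5.29 and 4.93 in replicates 1 and 2. A gene at or under the bound in 1 line is given as "at least" a fold, from the other line's mean over that bound, and no fold is given where both lines are under it. That held for 14411 genes, or 57.8% of those tested, 47 of which were called.

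Genes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2 groups, no covariate, two-sided), with Benjamini-Hochberg adjustment over all genes. A gene was called at an adjusted p under 0.05 and an absolute log2 difference of at least 1. The median residual SD was 0.0939 log2 units. Same-numbered replicates were treated as unpaired.

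The tested lists, 49 with 1271 of 1293 members measured, were ABC drug efflux transporters, neighbours of ABCB1, of ABCC1 and of ABCG2, drug uptake carriers, topoisomerases and their repair enzymes, anthracycline reductases, cytochromes P450, glutathione metabolism, NRF2 and antioxidant genes, metallothioneins, survival genes, death genes, p53 targets, the 3 lists of DNA repair, G1/S and DNA replication, G2/M and mitosis, CDK inhibitors, mesenchymal, epithelial junction, luminal, basal and stem cell markers, interferon-stimulated genes, NF-kB and cytokine genes, antigen presentation, collagens, integrins and laminins, matrix proteases, receptor tyrosine kinases, MAPK, TGF-beta and BMP, YAP and TEAD, WNT and NOTCH genes, hypoxia and glycolysis, oxidative phosphorylation, cholesterol and fatty acid synthesis, unfolded protein and ATF4 response, heat shock, autophagy and lysosome, ribosomal proteins, cancer-testis antigens, and leukocyte, endothelial, neural, and hepatocyte and gut markers. Each was tested against all other genes with camera at a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry, which asks if a list's genes move one way on balance, were run beside it. Windows of 5 Mb with at least 10 genes were tested in the same way as an exploratory result. Their medians are given over the brighter genes, those whose higher group mean was at or above the median over all genes.

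Genes were named by a rule: the 12 called genes with the largest rise and the 12 with the largest fall whose groups lay apart, without unnamed, antisense and small RNA loci, up to 2 called members per direction of each list, and ABCB1, ABCC1, ABCG2 and TOP2A whatever their values. A few genes that the rule takes are not reported here. The design, the lists, this rule and all alternatives but those named as added later were fixed before the data were examined.

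The fit was tested on simulated arrays of the 24930 genes for T24/THP against T24. With 50 genes per size, it called 0% of genes with a true log2 difference of 0.5, 100% at 1.25, 96% at 1.5 and 100% at 2, and 0 unchanged genes. Of 10 sets of 30 genes shifted by 0.5 all 10 passed, against 0 of 30 unshifted sets, and all 20 windows shifted by 0.3 passed. The simulated genes were independent of one another, so this does not show how often sets or windows of correlated genes pass falsely.

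The alternatives were the series table, quantile normalization, arrays centred on their medians, an offset of 32 on the linear scale, filters on dim genes at the 25th and the 50th percentile, other rules for several transcript clusters, other thresholds and tests, array weights, the replicate number as a block, windows of 2 and 10 Mb, list tests on ranks, and leaving out each array. Removal of the trend with level, 1 gene per symbol root in a window, windows without interferon-stimulated genes and the list of ABCG2 neighbours without them were added after the data were seen. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Transcript clusters without a gene symbol or annotation were left out of the gene test, since no gene could be named, and were fitted apart.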

Results

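The data were 6 Affymetrix whole-transcript arrays of total RNA, 3 of the human bladder carcinoma line T24 and 3 of T24/THP, which the labels give as a multidrug-resistant derivative of it. No genotype came with the data, so that descent could not be checked, and any difference between the lines that arose another way would be part of every value. T24/THP was raised per the labels by exposures of 24 h to pirarubicin, an anthracycline that traps topoisomerase II on DNA, at concentrations that climbed from 5 to 1000 ng/ml over more than 6 months. The resistant line was dosed again every 2 to 3 weeks to keep it resistant, and the parental line was cultured alongside. The labels call the 3 arrays of each line biological replicates from independent samples. Each line was derived once, so the p-values measure the spread between samples of these cultures and not between separate selections. The labels give no interval between the last dose and RNA extraction. The design asks which genes differed between the resistant and the sensitive line. Array medians lay between 3.71 and 3.79 log2 units, and Pearson's correlation over genes was 0.9967 to 0.9984 within a line and 0.977 to 0.981 between lines. The number of arrays, 3 per line, limits the precision of every value.

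Of the 12 genes with the largest measured rises in T24/THP, 8 stand on the list of interferon-stimulated genes and 3 encode cystatins, and KRTAP2-3 had the largest fall of genes above the background range in both lines. IFI27, an interferon-inducible mitochondrial protein, rose from 5.77 ± 0.25 to 16.93 ± 0.13 log2 units (SD, n = 3 each), a difference of 11.16 ± 0.129 (SE) or 2288-fold. CST4, a secreted cysteine protease inhibitor of the cystatin family, rose from 9.33 ± 0.12 to 17.36 ± 0.19, a 262-fold difference. KRTAP2-3, a keratin-associated protein, fell from 12.77 ± 0.21 to 7.02 ± 0.19, a 53.7-fold difference. FABP4, a fatty acid carrier of fat cells and of luminal urothelium, fell from 9.26 ± 0.08 to 3.45 ± 0.29, at least 13.5-fold. Of 24930 genes tested, 1651 passed an adjusted p of 0.05 with a difference of at least 2-fold, 710 higher and 941 lower in T24/THP.

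The other genes among the 12 with the greatest rises were RSAD2 (an antiviral enzyme), OAS2 and OAS1 (sensors of double-stranded RNA), IFI44L, IFI6, SAMD9L and IFIT1 (products of interferon-stimulated genes), CST1 and CST2 (cystatins), and ERP27 (a chaperone-binding protein of the endoplasmic reticulum). RSAD2 was at least 94.4-fold higher, OAS2 168-fold, IFI44L 162-fold, IFI6 99.8-fold, OAS1 at least 30.6-fold, SAMD9L 39.6-fold and IFIT1 at least 21.3-fold. CST1 was 73.5-fold, CST2 41.4-fold and ERP27 at least 23.9-fold higher. The cystatin genes are close paralogs, so their probes may share signal.

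The other genes among the 12 with the greatest falls included STC1 (a secreted glycoprotein hormone), which fell by 5.44 on the log2 scale, SEMA7A (a membrane-bound semaphorin), at least 25.7-fold lower, and THBS1 (thrombospondin 1, an inhibitor of angiogenesis), which fell by 4.14. SMR3B (a salivary secreted protein) was at least 7.12-fold lower, and GABBR2 (a subunit of the GABA-B receptor) was at least 6.85-fold lower. HBEGF, a growth factor that binds the EGF receptor, fell by 3.40, and CHAF1B, a subunit of the histone chaperone that follows DNA replication, fell by 3.34. FABP5P7 fell by 3.93 and FABP5P1 by 3.80. Both are pseudogenes of FABP5, and their probes may read the transcript of the parent gene. ANXA8L1, which has near-identical copies, fell by 3.75. Genes were ranked by the measured difference, also where one line lay in the background range. By their bounds FABP4 would stand below KRTAP2-3, STC1, SEMA7A, THBS1, FABP5P7 and FABP5P1, and SMR3B and GABBR2 below TYMS, which was 9.50-fold lower. Likewise RSAD2 would stand below OAS2, IFI44L and IFI6 among the rises, and ERP27 and IFIT1 below IFI44, an interferon-stimulated gene that rose by 4.77.

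The test was limma's moderated fit with Benjamini-Hochberg adjustment. Adjusted p was 2.49e-08 for IFI27, 3.67e-08 for CST4, 3.24e-07 for KRTAP2-3 and 3.84e-07 for FABP4. Without the minimum difference 8246 genes passed, and a test against a difference of 2-fold itself left 738. That test ended the calls of 43 of the genes named by rule, none of which differed by more than 1.59 log2 units, among them GSTP1, SLC7A11, CYCS, BIRC5, CDKN2A, LOX, CD44, COL4A1, HES1, SLC2A3, COX8A and NDUFB6. The excess of lower genes depended on the scaling, with 800 higher and 798 lower under quantile normalization, and 814 higher and 785 lower with the trend of the difference with level removed, a setting chosen after the data were seen. IFI27 (TC14000584.hg.1) lies on chromosome 14 at 94577079 to 94583033, CST4 (TC20000717.hg.1) on chromosome 20 at 23666277 to 23669677, KRTAP2-3 (TC17001485.hg.1) on chromosome 17 at 39215492 to 39216366 and FABP4 (TC08001365.hg.1) on chromosome 8 at 82390654 to 82395498, all in GRCh37. The median difference fell with level, from 0.02 for genes with a mean under 4 log2 units to −0.16 for genes at 12 and above.

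**Figure D1:**
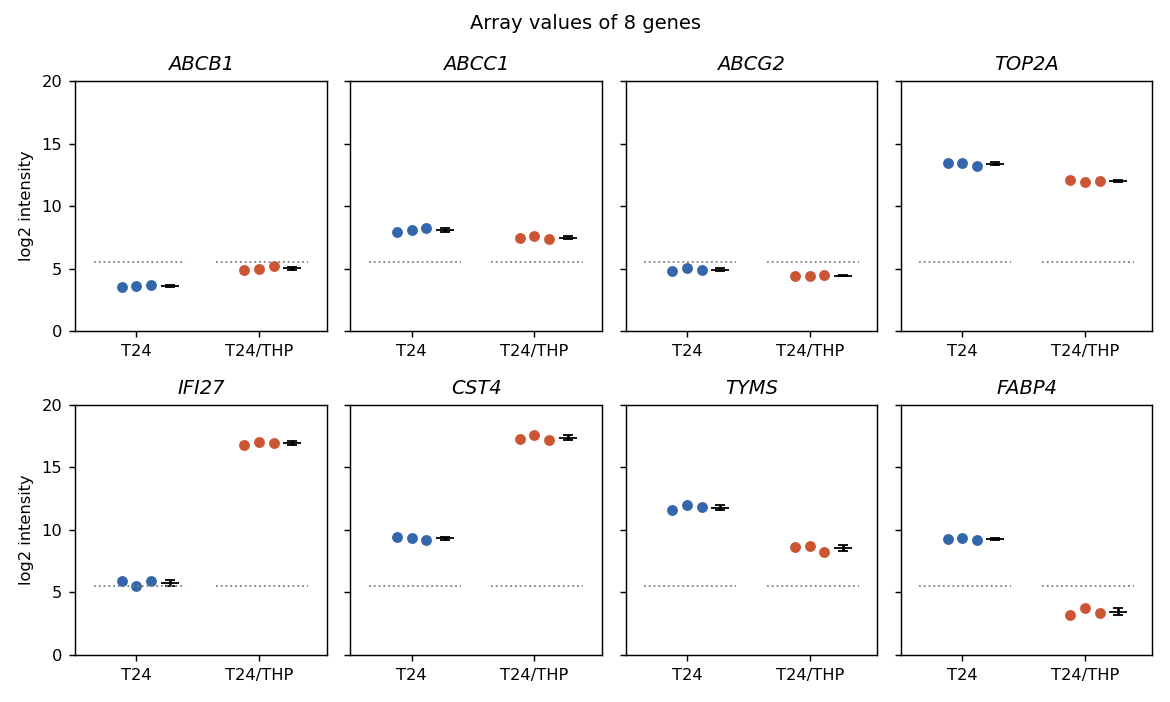
Log2 intensity of 8 genes on each array of T24 (blue) and T24/THP (red), with the mean ± SD of 3 arrays as bars and the upper bound of the background range, 5.54 in T24 and 5.51 in T24/THP, as dotted lines. ABCB1 and ABCG2 stayed under that bound in both lines, while IFI27 and CST4 rose to 16.93 and 17.36 in T24/THP.

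Among the transporters that pump anthracyclines out of cells, ABCB1 alone was called, at levels within the background range. ABCB1, which encodes P-glycoprotein, was 3.63 ± 0.09 in T24 and 5.04 ± 0.13 in T24/THP, both within the range of the background probe sets, so no fold is given. Its difference of 1.42 ± 0.084 (SE) passed the test, with an adjusted p of 1.64e-05, and shrank to 0.55 with an offset of 32 added to the linear values, which ended the call. An offset of that size shrinks any difference at such levels. In both lines ABCB1 lay above the median background probe set, which was 2.65 to 2.86 over the arrays. ABCC1, which encodes the pump MRP1, went from 8.09 ± 0.15 to 7.48 ± 0.10 (n = 3 each), a difference of −0.62 that was under the 2-fold minimum (adjusted p of 0.00126). ABCG2, which encodes the pump BCRP, was in the background range in both lines, at 4.92 ± 0.10 and 4.45 ± 0.07. TOP2A, which encodes the topoisomerase that anthracyclines poison, fell from 13.38 ± 0.13 to 12.01 ± 0.07, a 2.59-fold difference with an adjusted p of 1.64e-05. Its log2 difference was −1.37, and the list of G2/M and mitosis genes had a median of −1.55. A fall of that size was thus not particular to this drug target.

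ABCB1 (TC07001579.hg.1) lies on chromosome 7 at 87132948 to 87342639, ABCC1 (TC16000193.hg.1) on chromosome 16 at 16043434 to 16236931, ABCG2 (TC04001370.hg.1) on chromosome 4 at 89011416 to 89152474 and TOP2A (TC17001462.hg.1) on chromosome 17 at 38544768 to 38574408 (GRCh37). ABCB1 was the 1 called member of the 15 ABC drug efflux transporters measured, 10 of which were in the background range in both lines, and the list did not pass (adjusted p of 0.675). Of 13 neighbours of ABCB1 at 7q21.12, ADAM22 was at least 1.94-fold higher and DBF4, an activator of replication origins, fell by 1.12, and the list did not pass (adjusted p of 0.402). ADAM22 lost its call in 6 alternatives, among them without T24 replicate 2 (0.98) and without T24/THP replicate 2 (0.99) or 3 (0.97), and DBF4 missed it with quantile normalization (−0.98). Of 10 neighbours of ABCC1 at 16p13.11 only BMERB1 was called, at 1.83 (list adjusted p of 0.734). Of 10 neighbours of ABCG2 at 4q22.1, 3 rose and 1 fell, and 4 were called when adjusted over the list alone. That list passed (adjusted p of 0.0269; adjusted p = 0.820 with an estimated correlation). HERC5 rose 10.3-fold and HERC6 9.41-fold, and both are ubiquitin ligases that interferon induces and stand on the list of interferon-stimulated genes too. HERC3 fell by 1.02 and lost its call in 6 alternatives, among them without T24 replicate 3 (−0.92). The list lost its call on ranks (0.156), with genes filtered at the 50th percentile of level (0.140) and without T24 replicate 1 (0.0623). Without the members on the interferon list, an alternative chosen after the data were seen, the adjusted p was 0.525.

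Few enzymes and carriers that act on anthracyclines or on oxidants were called, and those that fell stood on the antioxidant, glutathione and topoisomerase lists. Of 22 genes on the list of NRF2 and antioxidant genes 6 fell and 1 rose, with a median of −0.52, and 7 were called when adjusted over the list alone and 3 in the test against a difference of 2-fold itself. PRDX3, a mitochondrial peroxidase, fell by 1.94 and ME1, an NADPH-producing enzyme, by 1.39, while SOD2, the mitochondrial superoxide dismutase, rose 2.85-fold. The list passed (adjusted p of 0.00597; adjusted p = 0.698 with an estimated correlation), and not with the filter at the 50th percentile (0.0559). None of the 9 metallothioneins, which bind metals and oxidants, was called, nor when adjusted over the list alone, and their median was 0.18. That list passed narrowly (adjusted p of 0.0465; adjusted p = 0.820 with an estimated correlation), and lost the call with that filter (0.140), without T24 replicate 1 (0.0623) or 3 (0.168), and without T24/THP replicate 2 (0.108) or 3 (0.0769). Of 28 glutathione genes 3 fell, among them GSTP1, a glutathione transferase, at −1.17, and SLC7A11, the cystine importer, at −1.14 (list adjusted p of 0.940). SLC7A11 missed the 2-fold minimum with the level trend removed (−0.98). None of the 16 anthracycline reductases was called (0.290). CYP2J2 was the 1 called member of 20 cytochromes P450, at least 1.69-fold higher (0.701). SLCO4A1, an organic anion carrier, was the 1 called member of 16 drug uptake carriers, 2.61-fold higher (0.864). Of 12 topoisomerases and their repair enzymes 3 fell, TOP2A, RMI1 at −1.37 and TOPBP1 at −1.02, the last named after its values were seen (0.417).

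Genes of cell death and of the p53 response went both ways. TNFSF10, the death ligand TRAIL, rose at least 8.27-fold and BCL2L11, the killer protein BIM, 3.11-fold, while CYCS, cytochrome c, fell by 1.26 and BID by 1.05. CFLAR, an inhibitor of death receptor signalling, rose 3.04-fold and BIRC3 2.26-fold, while BCL2A1 was at least 1.51-fold lower and BIRC5, the mitotic protein survivin, fell by 1.22. Of 27 death genes 2 rose and 3 fell (list adjusted p of 0.704), and of 13 survival genes 3 rose and 2 fell (0.732). Of 24 p53 target genes 2 rose and 2 fell (0.782). TP53INP1, a stress-induced regulator of p53, rose 6.22-fold and PLK2 2.97-fold, while DDB2, which recognises ultraviolet lesions, fell by 1.90 and the nuclease AEN was at least 1.97-fold lower. With the offset of 32, BID (−0.84), BCL2A1 (−0.99) and AEN (−0.96) missed the 2-fold minimum, as did BID without T24 replicate 3 (−0.999).

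The interferon-stimulated genes rose as a group. Of 42 measured, 37 rose and none fell, with a median difference of 3.39, and 37 were called when adjusted over the list alone. IFI27 led the list. The remaining 5, ISG20, IFITM2, IFITM3, IRF1 and IRF9, differed by 0.34 to 0.73 and were named after their values were seen. The list had the lowest p of the 49 tested (adjusted p of 5.90e-37; adjusted p = 0.554 with an estimated correlation).

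On the list of genes that present antigens more rose than fell. Of 26 measured, 9 rose and 2 fell, 11 called when adjusted over the list alone and 7 against a 2-fold difference itself, with a median of 0.53, or 0.21 with levels in the background range set to its upper bound (adjusted p of 4.00e-05; adjusted p = 0.554 with an estimated correlation). The class I molecules HLA-B and HLA-C rose 5.52-fold and 3.34-fold. CD274, the checkpoint ligand PD-L1, fell by 1.74 and the class II chain HLA-DPA1 by 1.46. Gene ontology terms, looked at after the data were seen, leaned the other way. Presentation of peptide antigen through class I was lower (10 genes rose and 15 fell of 97, median −0.16, adjusted p of 0.0253; adjusted p = 0.948 with an estimated correlation), as was its exogenous, TAP-dependent part (8 rose and 14 fell of 75, median −0.30, 0.0161; adjusted p = 0.948 with an estimated correlation). Of these 97 and 75 genes only 17 and 16 stand on any of the tested lists. Most members of the terms are thus not on the antigen presentation list, and the terms do not show that its genes fell. HLA genes are polymorphic paralogs, so their probes may share signal.

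NF-kB and inflammatory cytokine genes fell on balance. Of 40 measured, 15 fell and 5 rose, 20 called when adjusted over the list alone and 10 against a 2-fold difference itself, with a median of −0.39 (adjusted p of 0.00815; adjusted p = 0.820 with an estimated correlation). The list lost its call with the filter at the 50th percentile (0.0802). CSF3, which drives granulocyte production, fell by 3.19 and the neutrophil attractant CXCL8 was 5.83-fold lower. CXCL10 rose at least 8.86-fold and CXCL11 at least 4.79-fold, and both are T cell attractants that interferon induces. Of 27 leukocyte markers 1 was called, the lysosomal protein CD68, 2.18-fold higher, and 25 were in the background range in both lines (list adjusted p of 0.652).

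**Figure D2:**
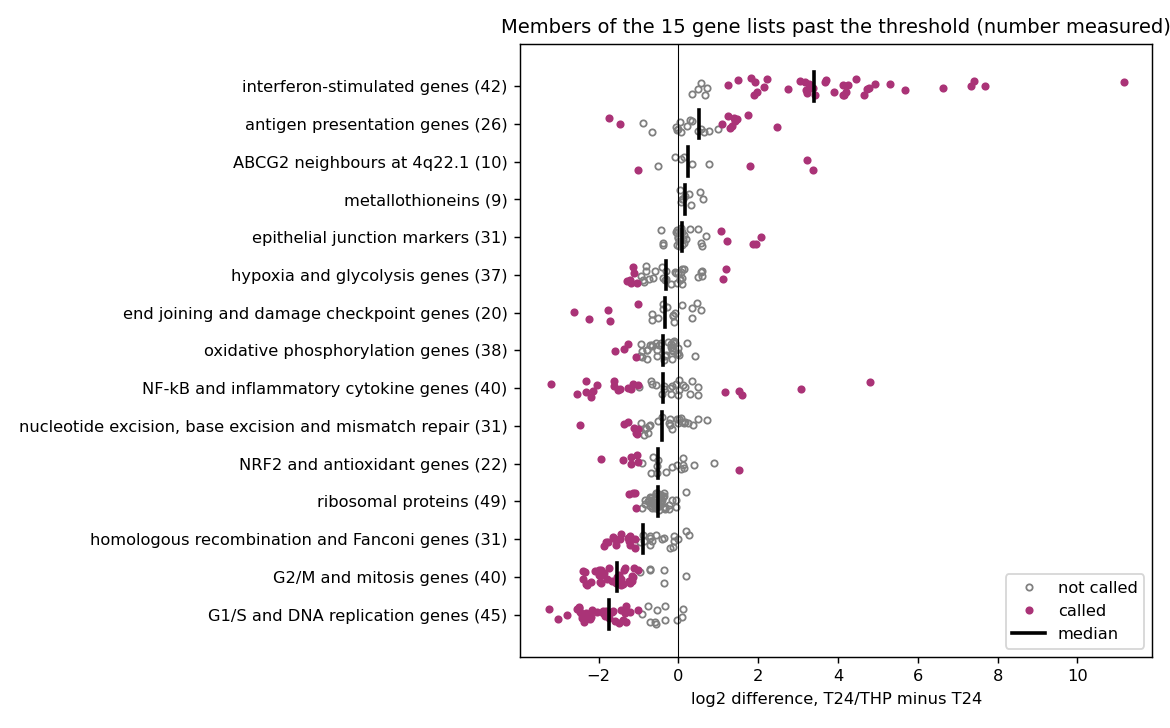
Log2 difference, T24/THP minus T24, of each measured member of the 15 gene lists past the threshold, with called genes filled and the median of each list as a bar. The median was 3.39 for interferon-stimulated genes and −1.73 for G1/S and DNA replication genes, and the numbers in parentheses are measured members.

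Genes of DNA replication and mitosis fell as groups. Of 45 G1/S and DNA replication genes 34 fell and none rose, with a median of −1.73, and of 40 G2/M and mitosis genes 34 fell and none rose, with a median of −1.55. TYMS, which makes thymidylate, fell from 11.78 ± 0.19 to 8.53 ± 0.24 (n = 3 each), a 9.50-fold difference, and GINS2, a part of the replicative helicase, was at least 7.17-fold lower. The kinetochore gene NDC80 was 5.25-fold lower and the chromosome motor KIF4A 5.24-fold lower. CDKN2B and CDKN2A, which encode inhibitors of CDK4 and CDK6, rose 4.66-fold and 2.10-fold among 8 CDK inhibitors, with 2 called and a list adjusted p of 0.734. With the offset of 32 CDKN2A was at 0.86.

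Adjusted over the list alone, 34 members were called in each of the G1/S and the G2/M list. The G1/S list passed (adjusted p of 5.54e-23; adjusted p = 0.685 with an estimated correlation), as did the G2/M list (adjusted p of 1.64e-24; adjusted p = 0.554 with an estimated correlation). No list passed with a correlation estimated from these 6 arrays.

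DNA repair genes fell too, and many of them are known to peak in S phase. Of 31 homologous recombination and Fanconi genes 14 fell and none rose, 14 also when adjusted over the list alone and 5 against a 2-fold difference itself, with a median of −0.88 (adjusted p of 1.48e-10; adjusted p = 0.698 with an estimated correlation). FANCI, a part of the crosslink repair complex, fell by 1.86 and RAD54L, a recombination motor, by 1.80. Of 31 genes of nucleotide excision, base excision and mismatch repair 7 fell, 7 when adjusted over the list alone, with a median of −0.42 (adjusted p of 0.000518; adjusted p = 0.820 with an estimated correlation). Without T24 replicate 2, and also with quantile normalization, 4 were called, and 2 against a 2-fold difference itself. The flap nuclease FEN1 was 5.52-fold lower. Of 20 end joining and damage checkpoint genes 5 fell, 5 when adjusted over the list alone, with a median of −0.33 (adjusted p of 0.00668; adjusted p = 0.820 with an estimated correlation, and 0.136 with the filter at the 50th percentile). CLSPN, an adaptor of the replication checkpoint, was 6.16-fold lower and H2AX, the histone that marks breaks, 4.71-fold lower.

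Genes of protein synthesis and respiration fell by smaller amounts. Of 49 ribosomal proteins 45 differed at an adjusted p under 0.05 and 4 of these fell at least 2-fold, with a median of −0.52. RPS13 fell by 1.13. Of 38 oxidative phosphorylation genes 4 fell, with a median of −0.39, among them COX8A, a subunit of cytochrome c oxidase, which fell by 1.58, and NDUFB6, a subunit of complex I, which fell by 1.36. Of 37 hypoxia and glycolysis genes 6 fell and 2 rose, with a median of −0.30. DDIT4, an inhibitor of mTORC1, fell by 1.29 and the glycolytic enzyme PGAM1 by 1.21, while the glucose carrier SLC2A3 rose 2.29-fold and NDRG1 2.17-fold.

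All 3 lists passed. Ribosomal proteins had an adjusted p of 3.10e-16 (adjusted p = 0.698 with an estimated correlation), oxidative phosphorylation 3.66e-07 (adjusted p = 0.698 with an estimated correlation) and hypoxia and glycolysis 0.0154 (adjusted p = 0.820 with an estimated correlation). Adjusted over the list alone, 4, 4 and 8 members were called. In the test against a difference of 2-fold itself 0 ribosomal, 0 oxidative phosphorylation and 0 hypoxia genes were called. These lists hold bright genes, for which the median of all genes was also below 0, at −0.15 for genes of 10 to 12 log2 units. With that trend of the difference with level removed, an alternative chosen after the data were seen, the ribosomal median was −0.42, 2 ribosomal genes were called, RPS13 was at −0.93, and the hypoxia list lost its call (median −0.12, adjusted p of 0.0625). Quantile normalization also left 2 ribosomal genes. The hypoxia list lost its call with the filter at the 50th percentile (0.142), and with the offset of 32 it had 5 called genes, with NDRG1 at 0.98.

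Other lists of metabolism and stress did not pass. Of 32 cholesterol and fatty acid synthesis genes STARD4 and SCD were called, 2.41-fold and 2.01-fold higher (list adjusted p of 0.790). Of 37 unfolded protein and ATF4 response genes 1 rose, NUPR1 at 1.35, and 3 fell, among them the amino acid carrier SLC7A5 at −1.55 and CHAC1 at −1.17 (0.269). Of 23 heat shock genes 3 rose, with HSPB1 at 1.20 and HSPA1A at 1.10, and 1 fell, the mitochondrial chaperone HSPA9 at −1.01 (0.805). Of 41 autophagy and lysosome genes 3 rose, with GABARAPL1 3.88-fold and ATG14 3.41-fold higher, and 1 fell, the protease CTSL at −1.07 (0.224). The autophagy list passed with quantile normalization, at 0.0185, and with the level trend removed, at 0.0234. Some of these calls missed the 2-fold minimum elsewhere. SCD did so with centred arrays (0.94), without T24 replicate 2 (0.91) or 3 (0.94) and without T24/THP replicate 3 (0.99). HSPA9 did so with quantile normalization (−0.91), the level trend removed (−0.84), without T24 replicate 2 (−0.94) and without T24/THP replicate 1 (−0.99). HSPA1A was at 0.89 without T24 replicate 1, CTSL at −0.98 without T24 replicate 3, and with the offset of 32 CTSL was at −0.84 and CHAC1 at −0.96.

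A few junction genes rose, while most of their list lay in the background range. Of 31 epithelial junction markers 5 rose and none fell, 5 when adjusted over the list alone and 3 against a 2-fold difference itself, with a median of 0.09 (adjusted p of 0.0154; adjusted p = 0.698 with an estimated correlation). The tight junction gene CLDN1 rose 4.23-fold and the desmosomal gene PKP2 3.87-fold. On this list 20 genes were in the background range in both lines. With levels in that range set to its upper bound, the medians of the lists past the threshold were −0.03 for epithelial junctions and for the neighbours of ABCG2, 0.11 for metallothioneins, −0.11 for hypoxia and glycolysis and −0.37 for NF-kB, and the others but antigen presentation kept theirs. The −0.03 is the gap between the bounds of the lines, which any gene in the range in both takes, and stands for no difference.

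Mesenchymal and urothelial markers went both ways. VIM, the intermediate filament vimentin, rose from 7.13 ± 0.13 to 10.64 ± 0.18 (n = 3 each), 11.4-fold, and the collagen crosslinker LOX 2.55-fold, while the transcription factor SNAI2 fell from 7.06 ± 0.19 to 6.05 ± 0.28. SNAI2 lost its call in 6 alternatives, among them without T24 replicate 2 (−0.90) and without T24/THP replicate 1 (−0.85). Of 27 mesenchymal markers 2 rose and 2 fell (list adjusted p of 0.780). Of 21 luminal urothelial markers 1 rose, CYP2J2, and 1 fell, FABP4 (0.675). Of 23 basal and squamous markers 1 rose, the elastase inhibitor PI3, at least 3.63-fold, and 2 fell, the laminin chain LAMB3 at −1.32 and the hyaluronan receptor CD44 at −1.27 (0.675). The CD44 difference was −0.94 as the mean over its transcript clusters. Of 24 stem cell markers 2 rose and 3 fell (0.412). LGR5, a receptor of R-spondins, rose at least 7.43-fold and KLF5 2.56-fold, while ALDH1A3, a retinaldehyde dehydrogenase, fell by 2.00 and ITGA6 by 1.37.

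Matrix and adhesion genes were called in both directions, and their lists did not pass. Of 30 integrins and laminins 5 rose, with ITGB8, which activates latent TGF-beta, 12.5-fold and ITGA10 at least 1.84-fold higher, and 2 fell, ITGA6 and LAMB3 (adjusted p of 0.0673). That list passed with quantile normalization, at 0.0260, and with arrays centred on their medians, at 0.0394 and a median of −0.02, and with the level trend removed, at 0.0203. PLAT, tissue plasminogen activator, rose 11.3-fold among 33 matrix proteases and inhibitors, of which 1 rose and 4 fell (0.675), with the collagenase MMP13 at least 3.80-fold and MMP14 3.70-fold lower. Of 31 collagens 1 rose, COL14A1 within the background range, and 2 fell, COL4A2 at −1.19 and COL4A1 at −1.15 (0.864). With the offset of 32 all 3 missed the 2-fold minimum, at 0.66, −0.94 and −0.86.

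Signalling lists held single large changes and none passed. JAG1, a ligand of NOTCH receptors, fell by 3.27 and the NOTCH target HES1 by 1.15, and DTX3L, a ubiquitin ligase that interferon also induces, rose 5.73-fold, with 1 up and 2 down of 28 (list adjusted p of 0.790). FOSL1, a subunit of AP-1, fell by 2.51 and IER3 by 1.37, while the feedback inhibitor SPRY1 rose at least 1.63-fold, with 1 up and 3 down of 32 MAPK output genes (0.652). INHBA, a subunit of activin A, fell by 2.29 and TGFB2 rose 3.48-fold, with 3 up and 3 down of 29 TGF-beta and BMP genes (0.892). INHBB, at least 2.02-fold higher, had an adjusted p of 0.0490 and lost its call in 11 alternatives, among them an adjusted p under 0.01 as the threshold, leaving out each of the T24 replicates (0.139, 0.117 and 0.0529) and leaving out T24/THP replicate 2 (0.0762) or 3 (0.0535), the last with a difference of 0.79. HES1 was at −0.93 with the offset of 32. NT5E, the ectonucleotidase CD73, rose 6.77-fold and ANKRD1 2.63-fold, while FJX1 fell by 1.75, with 4 up and 1 down of 26 YAP and TEAD targets (0.675). WNT5A was at least 1.41-fold lower and the receptor gene FZD8 2.98-fold lower, while FZD4 rose 3.51-fold and DKK3 2.46-fold, with 4 up and 2 down of 40 WNT genes (0.704). MERTK rose 2.95-fold, EPHB2 was at least 2.72-fold and TIE1 at least 2.28-fold lower, with 1 up and 2 down of 40 receptor tyrosine kinases (0.675).

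Lists of markers of other tissues did not pass the test. Of 16 endothelial markers 3 fell, among them TIE1 and ROBO4, the latter within the background range (list adjusted p of 0.290). Of 23 neural and neuroendocrine markers 3 rose, among them the adhesion molecule L1CAM, at least 2.53-fold, and SNAP25, at least 1.15-fold (0.417). With the offset of 32 ROBO4 was at −0.65 and SNAP25 at 0.64. None of 24 hepatocyte and gut epithelium markers (0.780) and none of 29 cancer-testis antigens (0.675) was called. In 9 of the 34 lists that did not pass, the median, the mean and the test differed in sign, and in none of the 15 that passed. Adjusted over the list alone, each of the 49 lists had as many called members as over all genes.

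Genes of a few chromosome regions moved together in the test at the preset correlation, while no window passed with an estimated one. On chromosome 14 all 6 windows between 50 and 80 Mb were higher in T24/THP, with medians of 0.13 to 0.34 over all their genes and 0.30 to 0.76 over those brighter than the median gene, as was the window from 90 to 95 Mb that holds IFI27. On chromosome 11 a total of 7 windows were lower, from 15 to 20 Mb to 125 to 130 Mb, with medians of −0.025 to −0.17 over all their genes and −0.38 to −0.66 over the brighter ones. On the X chromosome 3 windows were lower, with medians of −0.046 to −0.094 over all their genes and −0.45 to −0.93 over the brighter ones. ATG14 is among the 8 called genes from 55 to 60 Mb on chromosome 14, and all 8 rose.

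Windows of 5 Mb with at least 10 genes were tested against all other genes, 562 in total. Of these 26 passed, 14 higher and 12 lower. The other windows that were higher lay on chromosomes 1, 7, 12, 15 and 19, and the others that were lower on chromosomes 10 and 17. On chromosome 19 the window from 50 to 55 Mb lost its call without T24 replicate 1 (0.0551) or 3 (0.0872), without T24/THP replicate 2 (0.0510) or 3 (0.0589) and on ranks (0.0745). It also lost it with the level trend removed (0.0913) and with 1 gene per symbol root (0.365), both chosen after the data were seen. The window from 125 to 130 Mb on chromosome 10 lost its call without T24 replicate 1 (0.0532), without T24/THP replicate 2 (0.0762) and on ranks (0.0896), and that from 195 to 200 Mb on chromosome 1 without T24 replicate 1 (0.0579). From 85 to 90 Mb on chromosome 1 the call was lost on ranks (0.0736) and, in alternatives chosen after the data were seen, with 1 gene per symbol root (0.325) and without the interferon-stimulated genes (0.0775). The window from 90 to 95 Mb on chromosome 7 (adjusted p of 1.96e-05, 6 called genes, all higher) holds SAMD9L and adjoins the window of ABCB1, which did not pass. The window from 20 to 25 Mb on chromosome 19 had the lowest p (adjusted p of 5.79e-06). Chromosome 11 as a whole was lower (adjusted p of 0.0151; adjusted p = 0.331 with an estimated correlation), with 109 genes lower and 27 higher, chromosome 14 was higher (0.0354; adjusted p = 0.409 with an estimated correlation), with 51 higher and 10 lower, and the X chromosome was lower (0.0366; adjusted p = 0.409 with an estimated correlation), with 56 lower and 11 higher. No window passed with an estimated correlation, and 18 passed without T24 replicate 1, which ended the call of 4 of the 14 windows on chromosomes 11 and 14, among them 50 to 55 Mb on chromosome 14. On ranks 3 of these 14 lost their call, 75 to 80 Mb (0.0775) and 115 to 120 Mb (0.0676) on chromosome 11 and 90 to 95 Mb on chromosome 14 (0.0961), the first of them also with the filter at the 50th percentile (0.0554). On the X chromosome the window from 20 to 25 Mb lost its call without T24 replicate 1 (0.0606) or 3 (0.0781), without T24/THP replicate 2 (0.0514) and on ranks (0.0820), and that from 15 to 20 Mb without T24 replicate 3 (0.0941) or T24/THP replicate 2 (0.0510). Without the interferon-stimulated genes, an alternative chosen after the data were seen, the window that holds IFI27 lost its call, at 0.0737.

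**Figure D3:**
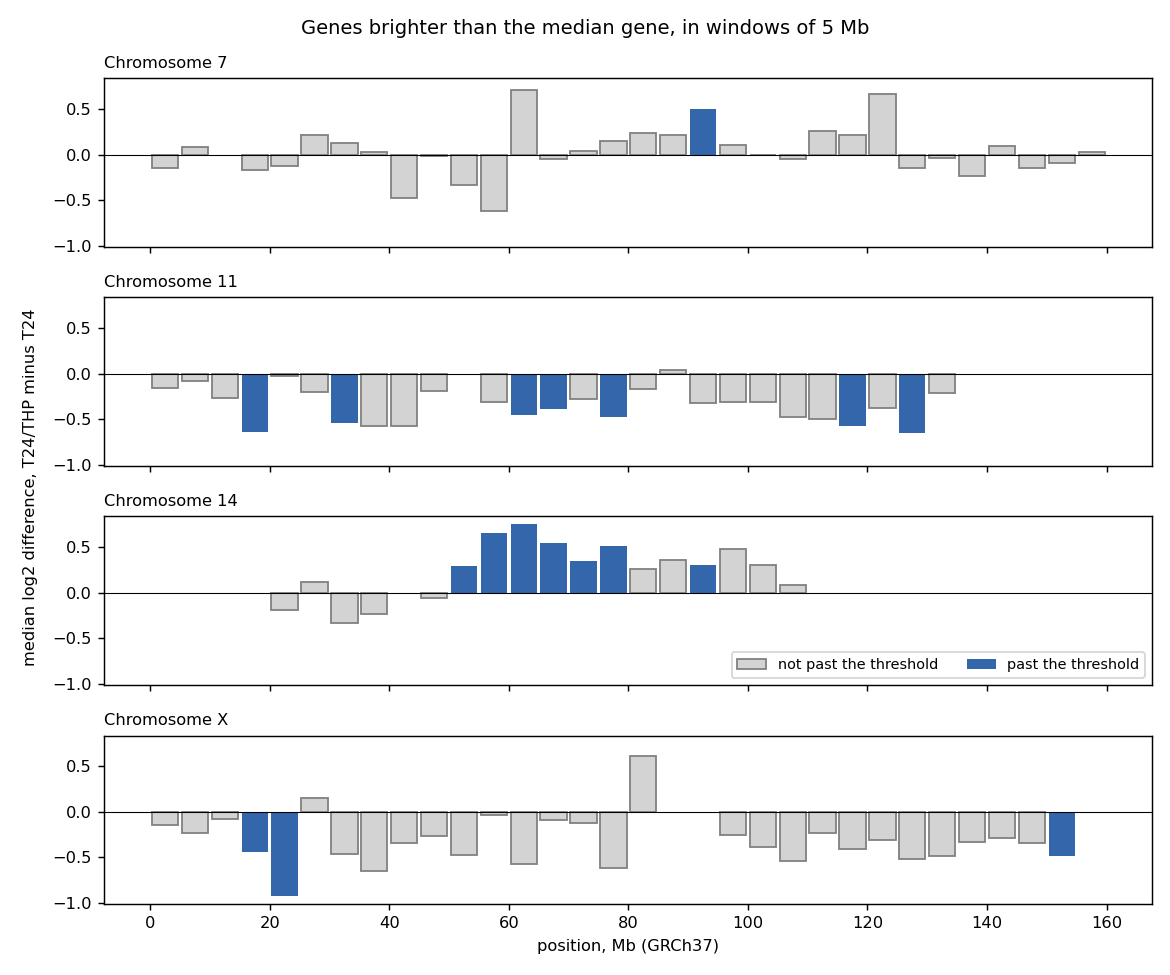
Median log2 difference, T24/THP minus T24, over the genes brighter than the median gene in windows of 5 Mb along chromosomes 7, 11, 14 and X (GRCh37 positions in Mb), with windows past the threshold in blue. The 6 adjoining windows from 50 to 80 Mb on chromosome 14 had medians of 0.30 to 0.76 over these genes and 0.13 to 0.34 over all their genes.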

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

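The tests of technical and biological explanations in this part were all chosen after the results were seen. What was to be read from the other splits of the samples was also set after that.

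Signal outside the gene test drew attention because it differed between the lines in data not used for the comparison. Among 39171 transcript clusters with no gene symbol, 686 were higher and 336 lower in T24/THP at the same thresholds. Of 24322 intergenic ones 409 were higher and 81 lower. The strongest lay in the exons of named genes, such as IFI27 at 10.82 and MX1 at 7.07, chosen after their values were seen, and the strongest intergenic one, on chromosome 19 at 23734519 to 23741642 (GRCh37), was 5.13 higher. Among 1674 transcript clusters without annotation, 50 were higher and 34 lower.

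The rise of interferon-stimulated genes was weighed first. A trend of the difference with level does not account for it, since the list's median was 3.49 with the trend removed and its lower quartile 2.13. White blood cells in the T24/THP cultures are argued against by the leukocyte markers, whose median difference was 0.0418 with an upper quartile of 0.0812, although 25 of 27 were in the background range. An interferon gene transcribed in T24/THP remains open, since 0 of 21 interferon genes measured were called but all were at background level, and interferon can act at amounts of transcript that arrays miss. Among them IFNE went from 3.08 in T24 to 3.66 in T24/THP, both within the background range. Its difference of 0.58 had an adjusted p of 0.00448 in the gene test and was under the 2-fold minimum. The hypothesis that selection left an interferon response switched on, or that the latest dose did, was not tested, because the labels give no time since the last dose.

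The fall of cell cycle genes was weighed next. With the trend with level removed, the median of the 85 genes on both cell cycle lists went from −1.66 to −1.53, with an upper quartile of −1.02, so the trend is not the whole cause. A smaller share of cycling cells in T24/THP is a candidate explanation, since replication-dependent histone genes, transcribed in S phase and on neither list, had a median of −1.31 over the 49 above background (upper quartile −0.54). Over all 61 the median was −1.17, or −0.74 with levels in the background range set to its upper bound. Of these 61, 33 fell and 4 rose, with H4C8 highest at 4.29. The histone values cannot tell a smaller share of cycling cells from lower levels of these transcripts in each cycling cell. Whether a smaller cycling share would come from slower growth of the line, from the last dose or from denser cultures stays open, as no growth data were used here.

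The windows of chromosomes 11 and 14 were weighed last. The trend with level does not account for them, since 14 of 14 stayed past the threshold with it removed. Probes shared by neighbouring genes of a family do not either, since 14 of 14 stayed past with 1 gene per symbol root. A loss of most of chromosome 11 and a gain of chromosome 14 beyond 50 Mb are candidate explanations, since the windows that did not pass leaned the same way, with a median over brighter genes of −0.273 for 19 on chromosome 11 and 0.304 for 5 on chromosome 14, against −0.0304 for 507 on other chromosomes (one-sided permutation p of 0.0001, the smallest that 10000 draws can give, and 0.0011). Neighbouring windows were treated as independent, their shared regulation would give the same values, and no DNA copy number was measured. Both regions and their directions were picked from these same data, and the permutation p-values are not corrected for that choice. Over all its brighter genes the X chromosome had a median of −0.336, near the −0.356 of chromosome 11.

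The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.1. The real split called 1651 genes and the highest of the others 0, with 1 split as large. It gave 26 windows against 7, again with 1 split as large. It gave 15 lists, and the highest of the others also gave 15, so 2 splits were as large. That other split set T24 replicate 1 with T24/THP replicates 1 and 3 against the rest, and follows no batch given in the labels. Every other split gave at least 4 lists. A group of 3 cannot hold both lines equally, so part of the difference between the lines stays in each of those splits. Their counts thus do not show how often a list passes at the preset correlation without such a difference. Every other split also mixes the lines within its groups, which widens the residual spread and made called genes unlikely from the start.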

How the results depend on the processing

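The removal of the trend with level, 1 gene per symbol root, and the leaving out of interferon-stimulated genes were chosen after the results were seen, and the other alternatives were planned. No list or window past the threshold in the main setting, and no named gene, turned the direction of its test where it was followed. Direction was not followed for the other lists and windows. The excess of lower over higher genes did turn, to 800 higher and 798 lower with quantile normalization and to 814 higher and 785 lower with the trend removed, and the cause was not tested. Of 137 named genes, 88 kept their direction and their side of the threshold in every alternative, and there were 97 cases of a lost call, 43 of them in the test against a difference of 2-fold itself. Without a minimum difference ABCC1 and ABCG2 passed, at −0.62 and −0.47. Called genes numbered 1598 with quantile normalization, 1706 with centred arrays, 1217 with an offset of 32 and 1599 with the trend removed, and 43.0% of calls were higher in the main setting, 50.1% with quantile normalization, 37.0% with centred arrays and 50.9% with the trend removed.

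Without a minimum difference 8246 genes passed, 3768 higher and 4478 lower, and a test against a difference of 2-fold itself left 738, 356 higher and 382 lower, both by the construction of the threshold. Leaving out 1 array gave 1590 to 1768 genes, 698 to 731 higher and 892 to 1048 lower, 13 to 15 lists and 18 to 29 windows, the 18 without T24 replicate 1.

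With an estimated correlation 0 lists and 0 windows passed. Camera then widens its errors by the correlation seen between genes over 6 arrays, and fry, which does not compare a list with other genes, passed 34. The lowest adjusted p of any list with an estimated correlation was 0.554. That setting was not run on the simulated arrays, so whether it could pass a truly shifted list here is not known. Keeping genes whose higher group mean was above the 50th percentile left 9 lists, and windows of 2 Mb gave 40. For those last values the cause was not tested. The 6 lists lost with that filter were the neighbours of ABCG2, NRF2 and antioxidant genes, metallothioneins, end joining, NF-kB, and hypoxia and glycolysis.

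With a replicate block 1653 genes (711 higher, 942 lower), 14 lists and 26 windows passed, 24 of the windows in the main setting too. Calls were lost by the neighbours of ABCG2, at 0.0549, and by the windows from 90 to 95 Mb on chromosome 14 and from 50 to 55 Mb on chromosome 19, both at 0.0561. The deviations of same-numbered samples from their line's mean correlated weakly, at 0.0396, 0.151 and 0.0186, and 4 of 6 samples were closest to their own number. These values neither show nor exclude pairing, and samples were treated as unpaired. Without interferon-stimulated genes 24 windows passed, and with 1 gene per symbol root 30.

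Signal over background limits the values of 14411 genes that lay in the background range in both lines, since for these a true difference would be compressed. Another 235 called genes lay in that range in 1 line.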

Other observations

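The gene families and gene ontology terms in this part were all chosen after the data were seen.

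Clustered protocadherin beta genes, which encode adhesion molecules of neurons from a tandem array on chromosome 5, were higher in T24/THP. Of 16 measured 10 rose and none fell, with a median of 1.64, or 0.47 with levels in the background range set to its upper bound, since 9 of the 10 were in that range in T24. PCDHB8 was 5.34 ± 0.06 in T24 and 8.58 ± 0.12 in T24/THP (SD, n = 3 each), at least 8.26-fold higher. Of 10 protocadherin alpha and gamma genes 1 rose. A count of 10 was also reached with quantile normalization, with centred arrays and with the trend with level removed. Among 1035 gene ontology terms of 15 to 300 genes, 144 passed, 11 higher and 133 lower, and none with an estimated correlation, where the adjusted p of each of the 144 was 0.948. Homophilic cell adhesion was higher (17 genes rose and 3 fell of 113, median 0.09, adjusted p of 5.44e-05). How many of those 17 were protocadherins was not counted, so the term is not separate evidence from that family. The terms that were lower were led by mitosis, DNA replication and translation, and for splicing through the spliceosome 24 genes fell and 3 rose of 163.

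Of 23 copies of SNORD116, a small nucleolar RNA of the imprinted region at 15q11 to q13, 18 rose, with a median of 2.09, or 0.72 with levels in the background range set to its upper bound, and 17 rose under each of the 3 other scalings. The copies are near-identical, so they are not independent measurements. None of 39 SNORD115 copies from the same region was called, with a median of 0.02. SNRPN, the host gene upstream, was 0.62 higher (adjusted p of 0.000276) and UBE3A differed by −0.32, both under the 2-fold minimum. The window from 25 to 30 Mb on chromosome 15 passed, and lost its call with 1 gene per symbol root, at 0.598.

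Of 12 type 2 cystatins 4 rose, CST1, CST2, CST4 and CST5, the last by 4.16, while CST3 was 0.94 higher and under the 2-fold minimum. With quantile normalization or with the trend removed 5 rose.

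Of 61 replication-dependent histone genes 33 fell and 4 rose. Those that rose were H4C8 at 4.29, H4C15 at 3.38, H2AC6 at 3.32 and H2BC21 at 1.91, under the main setting, and 4 also rose in each of the 3 other scalings. Some histone genes are also known to give polyadenylated transcripts in cells that do not divide, which was not tested.

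Of genes that sense or transmit interferon, EIF2AK2 rose by 1.86 and ADAR by 1.67, and both are bright genes known to be induced by interferon. DHX58 was at least 2.38-fold higher. The receptor gene TLR3 differed by 0.92, STING1 by 0.30, CGAS by −0.24, IFNAR1 by −0.29 and JAK1 by −0.14, none of them past the 2-fold minimum.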
